A study of Mus musculus with 16 samples.

How the data were processed

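RNA-seq was done on ear skin of 16 BALB/c mice, 4 in each of 4 groups made by treatment (LPC or saline vehicle) and day of killing (4 or 7). Groups and mouse numbers were taken from the sample titles, because the days in the deposited file names (3 and 6) differ from those in the titles. Each library came from a separate mouse, so the spread within a group is the spread between animals.

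Per the labels' protocols, the authors extracted total RNA with TRIpure, sequenced it on a BGISEQ-500 instrument, aligned reads with Bowtie2 to the mouse genome build GRCm38 and quantified genes with RSEM. The submitters' processing notes also name Bowtie2 and GRCm38, and versions are not given in the sources used here. Each deposited file lists, per gene, an RSEM expected count (an estimated count that need not be whole, because reads matching several genes are shared among them) and an FPKM value (fragments scaled to transcript length and to the library's mapped fragments), as made by the authors. RSEM divides reads of near-identical paralogs by a model, so values of such genes are less certain. A strand setting of the counting is not given in the sources used here. The lowest FPKM listed was 0.01, and a gene missing from a library's file was taken as 0 there. The files hold 19439 genes in at least 1 library and 15743 in all 16, identified by Entrez number, of which 19307 were in the reference annotation of GRCm38 used for symbols and positions.

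Total expected counts lay between 18704197 and 20131513 per library. Within groups, no pair of libraries agreed within sampling noise: the mean chi-square per gene was at least 19.98, and Pearson correlations of log2 values ran from 0.7781 to 0.9828. A gene without counts in a library could still be present at up to 3 counts, or 0.145 to 0.181 CPM. Such floors and the exact intervals of summed counts cover counting error only.

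Expected counts were rounded to whole numbers, and genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 15782 genes for testing and removed 3657. TMM factors ran from 0.836 (LPC day 7 mouse 1) to 1.107 (vehicle day 4 mouse 3). A quasi-likelihood model with a mean per group was fitted to all 16 libraries together (12 residual degrees of freedom, common dispersion 0.122, a biological coefficient of variation of 35%). The 5 comparisons were LPC against vehicle at day 4 and at day 7, day 7 against day 4 with vehicle and with LPC, and the difference of the LPC effect between the days. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and those that also changed more than 2-fold were counted separately, since the labels' protocols give that pair of criteria. Log2 fold changes carry standard errors from the edgeR model. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Principal components were computed from the 500 most variable genes.

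The comparisons, 38 gene lists and the rule for naming genes were fixed before the data were examined. Of 831 list symbols, 779 matched a gene, 10 of them by a synonym, and 36 lists were tested; the lists of mitochondrially encoded genes and of transcripts specific to a sex were not analysed here. For each list, members were counted at the adjusted p over all genes and with the adjustment over the list alone. Lists were also tested with camera in limma 3.58.1 (preset correlation between genes of 0.01, with the estimated correlation as an alternative) and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Where the median, the mean and the camera direction of a list differed in sign, camera did not call the list. List scores are the mean log2 CPM of the members per library and were compared by two-sided exact permutation tests, which for 4 against 4 can give no p below 0.0286, with adjustment over 36 lists.

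Named genes are the 8 with the largest rise and the 8 with the largest fall among called genes with an average log2 CPM of at least 1 and a proper symbol, up to 4 members with the smallest p of each list, the genes called at both days of LPC, and a fixed panel of cytokine, keratinocyte and LPC receptor genes. The test was checked on simulated counts with 15744 genes, of which 50 were changed at each fold size. The changed genes were drawn from those with an average log2 CPM above 1. Every gene was simulated independently, without the tissue differences that real libraries share. The simulated shares and false calls therefore do not give error rates for the real data. For LPC against vehicle at day 4, 40% of 2-fold, 84% of 4-fold, 94% of 8-fold and 100% of 16-fold changes were recovered, and 5 unchanged genes were called. For day 7 the shares were 48%, 78%, 92% and 96%, with 4 unchanged genes called.

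Alternatives fixed before the data were examined were median-of-ratios size factors, no low-count filter, a stricter filter (1 CPM in at least 8 libraries), DESeq2 1.42.0, limma-voom with sample quality weights, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), the mouse number as a block, fitting only the groups compared, the skeletal muscle score as a covariate, and leaving out each library in turn. Chosen after seeing the data were the muscle, adipocyte and hair follicle scores together as covariates, leaving out vehicle day 4 mouse 3 and LPC day 7 mouse 1 together, count ratios without the library holding the most counts, and the alternatives for list scores and for the genes called at both days of LPC. Counts for other splits of the libraries came from refits of the edgeR model. An adjusted p that DESeq2 did not give was left as missing. Exact intervals and figures were made with Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.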

Results

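The series holds RNA-seq libraries from the ear skin of 16 BALB/c mice, aged 8 weeks, during treatment with imiquimod (IMQ), an immune-activating drug that gives psoriasis-like inflammation when applied to mouse skin. Into the ear, mice received 10 µl of lysophosphatidylcholine (LPC, 10 mM), a phospholipid that has lost a fatty acid chain, or the same volume of saline as vehicle. Injections were planned at 1 per day over 6 days, and 4 mice of each treatment were killed on day 4 and 4 on day 7. The 4 groups are therefore vehicle day 4, LPC day 4, vehicle day 7 and LPC day 7, with 4 mice and 4 libraries each. Expected counts summed to between 18704197 per library (vehicle day 4 mouse 3) and 20131513 (LPC day 7 mouse 4), and between 17215 and 17730 genes were listed per library.

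Libraries differed in their levels of transcripts typical of non-epidermal tissues. The score of the skeletal muscle list (mean log2 CPM of 25 sarcomere and muscle metabolism genes) was 8.74 ± 1.70 in vehicle day 4, 4.43 ± 1.53 in LPC day 4, 7.31 ± 1.06 in vehicle day 7 and 6.41 ± 2.82 in LPC day 7 (mean ± SD, n = 4). Within LPC day 7 it was 8.76 and 8.85 in mice 2 and 4, against 4.69 and 3.33 in mice 1 and 3. Adipocyte scores were also higher in mice 2 and 4 of that group (5.23 and 7.16) than in mice 1 and 3 (2.13 and 2.64). The hair follicle score spanned -0.54 to 7.06 over the 16 libraries. The first 2 principal components of the 500 most variable genes held 40.7% and 36.2% of the variance. Muscle genes and the matrix metalloproteinases Mmp10, Mmp3, Mmp12 and Mmp13 had the largest loadings at the opposite ends of component 1, and hair keratin and keratin-associated genes had the largest on component 2. On component 1, vehicle day 4 lay between -50.8 and -16.5 and LPC day 4 between 12.2 and 42.4, while LPC day 7 spread from -26.5 to 50.2.

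**Figure D1:**
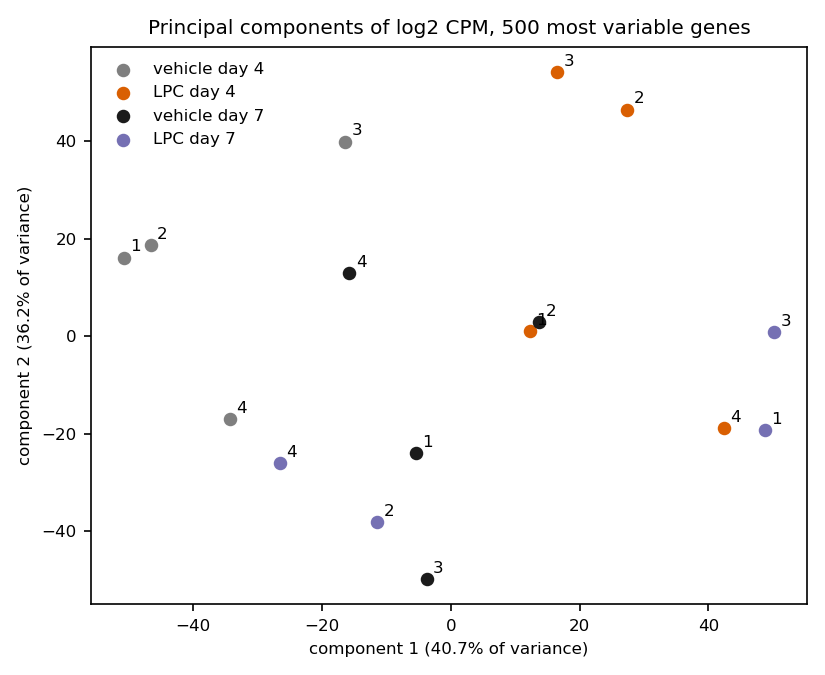
Each point is a library, numbered by mouse within its group, placed by its scores on principal components 1 and 2 (arbitrary units) of log2 CPM of the 500 most variable genes. Vehicle day 4 and LPC day 4 do not overlap on component 1, whereas the 4 LPC day 7 libraries spread from -26.5 to 50.2.

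At day 4, ear skin injected with LPC had more transcripts of a few tissue repair and stress genes than vehicle skin. Of 15782 genes tested, 15 rose and 7 fell, and 18 of these 22 changed more than 2-fold. Mmp10 (Entrez 17384, chromosome 9, 7502342 to 7510242 on GRCm38), a secreted protease of wound-edge keratinocytes, went from 1.24 ± 0.619 CPM in vehicle to 52.4 ± 35.7 CPM with LPC (mean ± SD, n = 4), a log2 fold change of 5.40 ± 0.97 (SE). Gdf15 (Entrez 23886, chromosome 8, 70629393 to 70632470), a stress-induced cytokine, rose by 3.11 ± 0.48 in log2 terms. Hmox1, the haem-degrading enzyme haem oxygenase 1, rose by 1.78 ± 0.32.

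Among called genes with an average log2 CPM of at least 1, the other risen genes with the largest changes were Rgs1, a regulator of G protein signalling in leukocytes, at 3.01 ± 0.46, and Adm, which encodes the vasodilator peptide adrenomedullin, at 2.49 ± 0.45 (log2 fold change ± SE, n = 4 per group). Atf3, a stress-induced transcription factor, followed at 2.46 ± 0.44, then Mgarp at 2.42 ± 0.44 and Unc13a at 1.64 ± 0.30. Adjusted p ranged from 0.025 to 0.046 over these 8 genes (edgeR quasi-likelihood test, Benjamini-Hochberg). The genes that fell at this level of expression were led by Asb16 at -3.15 ± 0.55, Gmpr at -2.44 ± 0.44 and the potassium channel genes Kcnc4 at -2.27 ± 0.35 and Kcnj2 at -1.73 ± 0.27. Tbx3, a developmental transcription factor, had -1.25 ± 0.23, and Liph, a phospholipase that makes lysophosphatidic acid, -1.24 ± 0.19. Their adjusted p lay between 0.025 and 0.048.

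In the list of tissue repair and matrix remodelling genes, Mmp10 alone of 25 members passed over all genes, and 13 rose when adjusted over the list alone. Mmp13 had a log2 fold change of 4.41 ± 0.88 (adjusted p = 0.056) and Mmp12, macrophage elastase, 4.31 ± 0.94 (adjusted p = 0.058). The list stood above other genes by camera (adjusted p = 5.5e-10), with adjusted p = 0.52 with an estimated correlation. Its score was higher in each of the 4 LPC libraries (5.45 ± 0.46) than in any vehicle library (3.91 ± 0.42), with an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.172 adjusted over 36 lists. Among 22 immediate early genes, which respond to growth factors and stress within the hour, Atf3 passed over all genes and 11 rose when adjusted over the list alone. Klf6 had 1.62 ± 0.36 (adjusted p = 0.058), Fos 2.18 ± 0.50 (adjusted p = 0.059) and Jun 1.45 ± 0.37 (adjusted p = 0.067). Camera gave this list an adjusted p of 1e-08, and adjusted p = 0.57 with an estimated correlation. Of 20 genes of the oxidative stress list, targets of the transcription factor NRF2, Hmox1 and Ugdh rose, and 7 rose when adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.52 with an estimated correlation). Among 20 genes of the unfolded protein and integrated stress response Atf3, which the immediate early list also holds, passed. Hspa5, an endoplasmic reticulum chaperone, had 1.07 ± 0.21 (adjusted p = 0.056).

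No member of the skeletal muscle list passed over all genes, and all 25 fell when adjusted over the list alone. Myoglobin (Mb) had a log2 fold change of -4.04 ± 0.89 (adjusted p = 0.058) and troponin gene Tnnt1 -4.12 ± 0.96 (adjusted p = 0.062). Camera placed the list below other genes (adjusted p = 5.5e-22, and adjusted p = 0.52 with an estimated correlation). Scores were 9.80, 9.32, 6.20 and 9.65 in vehicle mice 1 to 4 and 6.38, 2.96, 3.50 and 4.91 with LPC (exact permutation p = 0.0571). Of 19 adipocyte genes, none passed over all genes and 2 fell when adjusted over the list alone, with Slc2a4, the insulin-responsive glucose transporter, at -3.01 ± 0.71 (adjusted p = 0.064) and Lpl, lipoprotein lipase, at -1.99 ± 0.59 (adjusted p = 0.088). Camera placed this list below other genes (adjusted p = 1.5e-06, and adjusted p = 0.74 with an estimated correlation). Of 13 basal keratinocyte genes, none passed over all genes and 2 rose when adjusted over the list alone, among them Lama3, which encodes a basement membrane protein (1.18 ± 0.31, adjusted p = 0.069 over all genes). The IL-23/IL-17 list, whose cytokines drive psoriasis-like inflammation, had no member past the threshold among 23. Summed counts of Il17a were 60 in the 4 vehicle libraries, 56 of them in mouse 4, and 4 in the LPC libraries. Il22 had 76 counts with vehicle, 70 in mouse 4, and 3 with LPC, a ratio of 24.7 with a 95% Clopper-Pearson interval of 8.13 to 122 for counting error only. Without vehicle mouse 4 it was 2.61 (0.558 to 16.1).

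The day 4 count of 22 genes depended on the libraries and the model. It was 683 without vehicle mouse 3, whose muscle and neutrophil scores were the lowest of its group, 35 without LPC mouse 2 and 0 without any of the other 6 mice, and the muscle score as a covariate left 0 genes. Fitting the 8 day 4 libraries alone gave 1333 genes, DESeq2 1104, limma-voom with sample weights 1683, FPKM values 38 or 40, and no low-count filter 8.

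At day 7, LPC-injected skin had more transcripts of some tissue repair, NF-kB feedback and immediate early genes, and fewer of some terminal epidermal differentiation genes, than vehicle skin. The test called 604 genes, of which 376 rose and 228 fell, and 407 changed more than 2-fold. Csf3 (Entrez 12985, chromosome 11, 98700183 to 98703631), the granulocyte colony-stimulating factor, went from 5.58 ± 3.57 CPM with vehicle to 125 ± 126 CPM with LPC (mean ± SD, n = 4), a log2 fold change of 4.48 ± 1.10 (SE, adjusted p = 0.039). Krt2 (Entrez 16681, chromosome 15, 101810689 to 101818956), a keratin of the upper epidermis, fell by 4.24 ± 1.06, from 4071 ± 4820 to 215 ± 281 CPM. Vehicle mouse 4 had 11000.5 CPM of Krt2, and without it the log2 fold change was -3.03 (edgeR adjusted p = 0.14). Krt10 (Entrez 16661, chromosome 11, 99385254 to 99397449), the keratin of the suprabasal layers, went from 7794 ± 834 to 1650 ± 918 CPM. Leaving out a mouse of either group in turn ended the call of Csf3 in 6 of 8 cases (adjusted p from 0.028 to 0.11) and of Krt2 in 6 of 8 (0.032 to 0.14), and of Krt10 in 0 of 8 (0.012 to 0.048).

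Besides Csf3, the largest rises among called genes with an average log2 CPM of at least 1 were those of Nos2, the inducible nitric oxide synthase, at 3.88 ± 0.71, Tnfsf11, which encodes RANK ligand, at 3.58 ± 0.88, and Mmp10 at 3.51 ± 0.89. Areg, an epidermal growth factor receptor ligand, had 3.49 ± 0.93, Cxcl1, a neutrophil-attracting chemokine, 3.44 ± 0.84, the collagenase gene Mmp13 3.37 ± 0.85 and Fos 3.24 ± 0.52. Several of these differed widely between LPC mice: Csf3 had 286 and 164 CPM in mice 1 and 3 and 17.7 and 30.6 in mice 2 and 4. By the same limit, the 8 genes that fell the most were Krt2, the metallothionein gene Mt4 (-3.44 ± 0.73), Adh6a (-2.86 ± 0.57), Serpina12 (-2.81 ± 0.72) and the late cornified envelope genes Lce1l (-3.36 ± 0.75), Lce1k (-2.80 ± 0.53), Lce1h (-2.70 ± 0.57) and Lce1i (-2.70 ± 0.57). Lce1 genes are near-identical neighbours, so reads may have been divided between them and their separate values are uncertain. Adjusted p over these 16 genes ran from 0.011 to 0.049.

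Of 29 terminal epidermal differentiation genes, 10 fell and none rose over all genes, 14 fell when adjusted over the list alone, and 7 had a positive fold change. Camera placed the list below other genes (adjusted p = 2.4e-10, and adjusted p = 0.19 with an estimated correlation). Members included Krt10 (-2.24 ± 0.42, adjusted p = 0.015), the cornified envelope gene Hrnr (-2.14 ± 0.42, adjusted p = 0.018), Flg (filaggrin, -2.62 ± 0.65, adjusted p = 0.040) and Lor (loricrin, -2.26 ± 0.55, adjusted p = 0.037). List scores were 7.01 ± 0.24 with LPC and 8.21 ± 0.10 with vehicle, without overlap (exact permutation p = 0.0286, 0.129 adjusted over 36 lists). None of 13 basal keratinocyte genes passed over all genes and Dst fell when adjusted over the list alone (-0.71 ± 0.20, adjusted p = 0.065 over all genes). Of 23 sebaceous gland genes, Elovl6 (-1.92 ± 0.46) and Far2 (-1.65 ± 0.43), enzymes of fatty acid and wax synthesis, fell, and 12 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.2e-07, and adjusted p = 0.41 with an estimated correlation).

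Of 25 tissue repair and matrix remodelling genes, 13 rose, and 22 rose and 1 fell when adjusted over the list alone. Tgfb1 rose by 0.95 ± 0.16, the matrix protein gene Thbs1 by 1.80 ± 0.38 and the urokinase receptor gene Plaur by 2.52 ± 0.56, with adjusted p between 0.012 and 0.029. Among 20 genes of NF-kB feedback and endothelial activation 9 rose, among them Nfkbie (1.10 ± 0.18), Traf1 (1.74 ± 0.35) and Tnfaip2 (1.51 ± 0.31). Immediate early genes rose in 7 of 22 cases, led by the phosphatase gene Dusp1 (2.30 ± 0.35), the mRNA-destabilizing factor gene Zfp36 (1.72 ± 0.27) and Fos. Of 19 neutrophil genes 4 rose: Il1r2 (1.47 ± 0.32), Ly6g (3.17 ± 0.78), Hdc (2.40 ± 0.62) and Mmp9 (2.54 ± 0.67). Adjusted over the list alone, 15 of the NF-kB genes and 15 of the immediate early genes rose, and 16 of the neutrophil genes rose and 1 fell. Camera adjusted p was 7.3e-15 for repair, 2.6e-13 for NF-kB feedback, 1.5e-13 for immediate early and 4.6e-13 for neutrophil genes. With an estimated correlation it was adjusted p = 0.19 for each of the first 3 of these lists and adjusted p = 0.24 for neutrophil genes. Neutrophil scores were 6.90, 5.56, 6.70 and 5.22 in LPC mice 1 to 4 and at most 4.67 with vehicle (exact permutation p = 0.0286, 0.129 adjusted over 36 lists). Repair scores in LPC mice 1 to 4 were 6.75, 4.82, 6.49 and 4.78 (vehicle at most 4.43), immediate early scores 8.21, 6.49, 7.37 and 6.89 (vehicle at most 6.52, exact permutation p = 0.0571) and NF-kB feedback scores 6.91, 5.43, 6.37 and 5.75 (vehicle at most 5.12). All 4 lists had their higher values in mice 1 and 3, which had the lower muscle and adipocyte scores.

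Cytokine genes of the IL-23/IL-17 list mostly missed the threshold at day 7. Il6 had a log2 fold change of 4.38 ± 1.20 (adjusted p = 0.055), Tnf 1.89 ± 0.51 (adjusted p = 0.054) and Il17a 2.84 ± 1.30 (adjusted p = 0.24). Of the 23 members the receptor gene Il17ra rose (0.66 ± 0.14, adjusted p = 0.026), while Il1f5, which encodes the IL-36 receptor antagonist, fell by 1.11 ± 0.25 and Il22ra2, which encodes the soluble IL-22 binding protein, by 1.15 ± 0.30. Adjusted over the list alone, 4 rose and 2 fell (camera adjusted p = 0.086). In the inflammasome list Il18 fell by 1.43 ± 0.35, 4 rose and 1 fell of 17 when adjusted over the list alone, and Nlrp3 had 2.75 ± 0.95 (adjusted p = 0.12). In the list of LPC receptors and metabolism, 2 of 28 rose and 1 fell (3 rose and 2 fell when adjusted over the list alone). Pla2g7, a phospholipase of oxidized phospholipids, rose by 1.58 ± 0.25 (adjusted p = 0.010), and Gpr132, described as an LPC-responsive receptor, rose by 1.16 ± 0.29 (adjusted p = 0.040). Pla2g2f, an epidermal secreted phospholipase, fell by 1.22 ± 0.27 (adjusted p = 0.027).

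Interferon and macrophage genes differed between the LPC day 7 mice. Of 25 type I interferon response genes, Isg15 rose (2.49 ± 0.66, adjusted p = 0.048), and 21 rose when adjusted over the list alone (camera adjusted p = 9.1e-12, and adjusted p = 0.41 with an estimated correlation). Scores in LPC mice 1 to 4 were 4.63, 6.28, 5.09 and 7.43, and those of the macrophage list 4.49, 6.33, 4.39 and 5.85. In both lists the higher values belonged to mice 2 and 4, which also had the higher muscle and adipocyte scores. Of 25 macrophage genes, Fcgr3 (1.57 ± 0.32), Itgam (1.77 ± 0.46) and Spp1 (2.80 ± 0.73) rose, and 7 rose when adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.52 with an estimated correlation). Of 15 circadian clock genes, Dbp (-1.55 ± 0.35), Hlf (-1.50 ± 0.34) and Ciart (-1.64 ± 0.38) fell, and 6 fell when adjusted over the list alone (camera adjusted p = 7.6e-06, and adjusted p = 0.24 with an estimated correlation).

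The day 7 count fell to 45 genes when only the 8 day 7 libraries were fitted, to 178 with limma-voom and sample weights, and to 169, 159 and 111 without vehicle mouse 2, 3 or 4 and to 121 and 316 without LPC mouse 1 or 3. It was 1175 with the muscle score as a covariate and 1448 by DESeq2, and FPKM values called 246 rises and 276 falls with a pseudocount of 0.1, and 276 and 254 with 1. On the FPKM + 0.1 scale the median log2 fold change of all genes was -0.12, against 0.02 for the counts, so its rises and falls are relative to that shift.

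**Figure D2:**
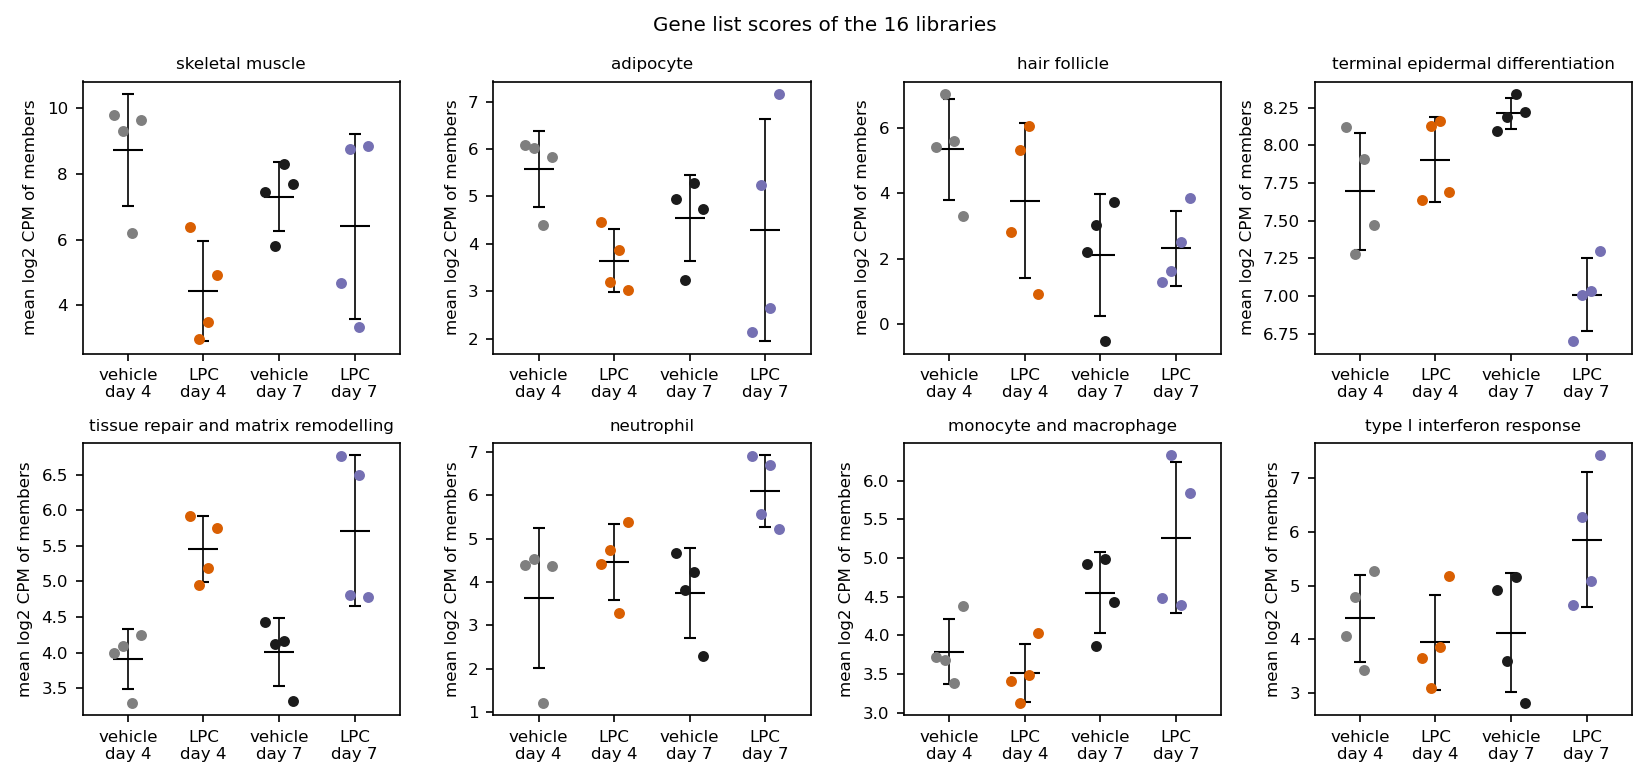
Points are the 16 libraries, 4 per group, and the y axis gives the mean log2 CPM of the list members; the dash and bars give the group mean and SD. Terminal differentiation scores of LPC day 7 (7.01 ± 0.24) lie below all vehicle day 7 libraries, and skeletal muscle scores span 3.33 to 8.85 within LPC day 7.

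The LPC effects of the 2 days, which share no library, overlapped in 5 risen genes. Rgs1, Gdf15, Adm, Hmox1 and Mmp10 were called at both days. Independent lists of 15 and 376 genes among 15782 would be expected to share 0.357 rises (Fisher's exact test, one-sided, p = 1.8e-05). That test takes genes as independent draws, yet genes vary together and both lists come from the same fit with shared dispersions. Its p therefore does not measure how often such an overlap would arise between mice. No gene fell at both days. At day 7 the log2 fold changes were 2.65 ± 0.45 for Rgs1, 2.37 ± 0.47 for Gdf15, 2.08 ± 0.44 for Adm and 1.36 ± 0.32 for Hmox1 (± SE). Of the 22 genes called at day 4, 16 had the same sign at day 7, and of the 604 called at day 7, 415 had the same sign at day 4. Across the 15782 genes, which are not independent replicates, the log2 fold changes of both days had a Pearson r of 0.11. The 5 shared genes became 111 by DESeq2 and 15 by limma-voom, 2 without a low-count filter, and 0 with the muscle score as a covariate or when each day was fitted alone.

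**Figure D3:**
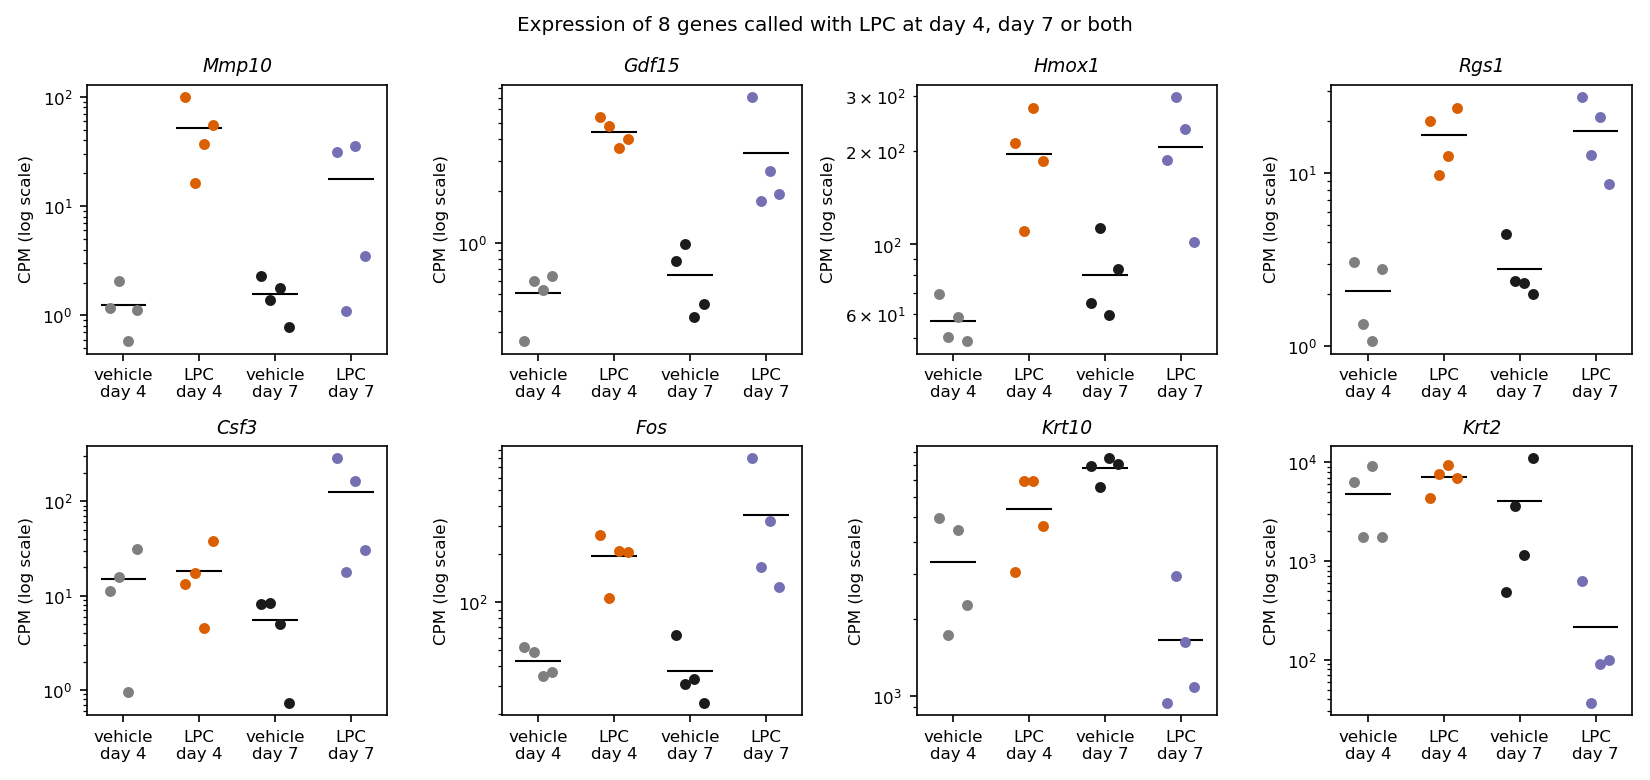
Points are CPM values on a log axis of 8 genes in the 16 libraries, and lines are group means of 4. Mmp10 goes from 1.24 to 52.4 CPM at day 4, and Krt10 from 7794 to 1650 CPM at day 7, between vehicle and LPC.

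Between day 4 and day 7 vehicle-injected, IMQ-treated skin showed no gene past the threshold. edgeR called 0 of 15782 genes (lowest adjusted p = 0.16, 2050 genes at an unadjusted p under 0.05), DESeq2 223 and limma-voom with sample weights 2489. Of 30 cell cycle genes, 23 rose when adjusted over the list alone, such as Ccna2 (cyclin A2, 1.20 ± 0.33, adjusted p = 0.21 over all genes), Birc5 (survivin, 0.98 ± 0.28, adjusted p = 0.21) and the proliferation marker Mki67 (1.28 ± 0.39, adjusted p = 0.23). Of 30 hair follicle genes, 27 fell when adjusted over the list alone, such as Shh (-5.68 ± 1.08, adjusted p = 0.16) and Lef1 (-2.29 ± 0.69, adjusted p = 0.22), both regulators of hair growth.

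Camera placed the cell cycle list above and the hair follicle list below other genes, each with an adjusted p of 1.4e-20, and adjusted p = 0.29 with an estimated correlation. Cell cycle scores differed by 0.92 between the days (exact permutation p = 0.0857, 0.386 adjusted over 36 lists). Hair follicle scores were 5.35 ± 1.54 at day 4 and 2.11 ± 1.87 at day 7 (mean ± SD, n = 4, exact permutation p = 0.0571). Of 29 terminal differentiation genes, 9 rose when adjusted over the list alone, with Rptn (repetin) at 3.68 ± 0.72, Casp14 at 2.44 ± 0.44 and Krt1 at 2.22 ± 0.44, each at adjusted p = 0.16 over all genes (camera adjusted p = 1e-05, and adjusted p = 0.29 with an estimated correlation). Of 30 fibroblast and matrix genes, 7 rose when adjusted over the list alone, among them Loxl2 (1.14 ± 0.28) and Fbn1 (1.37 ± 0.34), each at adjusted p = 0.19 over all genes. Of 20 NRF2 genes, 4 did, including Cbr3 (0.66 ± 0.14) and Gsta2 (1.25 ± 0.27) at adjusted p = 0.16. Camera adjusted p was 2.6e-10 for the matrix list and 6.6e-05 for the NRF2 list, and adjusted p = 0.29 for each with an estimated correlation. The chemokine gene Ccl20 had -2.49 ± 0.76 (adjusted p = 0.23). Without vehicle day 7 mouse 4, which had the lowest neutrophil score of its group at 2.28, edgeR called 205 genes.

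Between day 4 and day 7 of LPC injection, a part of the macrophage and interferon genes went up while a part of the terminal differentiation, sebaceous, pigment cell and clock genes went down. The test called 1736 genes, of which 1084 rose and 652 fell, and 1135 changed more than 2-fold. Of 25 macrophage genes, 12 rose, led by Fcgr3 (2.47 ± 0.33), Itgam (2.56 ± 0.47), Fcgr1 (4.08 ± 0.83) and Ms4a7 (3.48 ± 0.73), with adjusted p between 0.0031 and 0.012. The macrophage list also leaned upwards over time with vehicle, where 23 of its 25 members were higher and 0 passed over all genes. Its median log2 fold change there was 0.74 (camera adjusted p = 8.7e-06, and adjusted p = 0.64 with an estimated correlation). Sebaceous genes likewise had a median of -0.45 with vehicle (camera adjusted p = 0.0044, and adjusted p = 0.72 with an estimated correlation). Of 25 type I interferon genes, 8 rose, including the antiviral genes Oas3 (3.21 ± 0.64) and Zbp1 (3.19 ± 0.77).

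The largest rises among called genes with an average log2 CPM of at least 1 were Ms4a4b (6.65 ± 1.55), Thrsp (5.93 ± 1.74), the cardiac actin gene Actc1 (5.76 ± 1.57), Tmem8c (5.53 ± 1.59), which encodes the muscle fusion protein myomaker, Ms4a4c (5.23 ± 1.39), the muscle gene Ky (5.06 ± 1.26), the interferon-induced GTPase gene Tgtp2 (4.80 ± 0.94) and Cd300e (4.64 ± 1.24). Ms4a4b, Ms4a4c and Tgtp2 have close paralogs that can share reads. These rises were uneven: in LPC day 7 mice 1 to 4, Ms4a4b had 0.301, 24.0, 1.14 and 48.9 CPM and Thrsp 0.12, 8.98, 0.217 and 143, with the higher values in the 2 mice with the higher muscle and adipocyte scores. Scores of the macrophage list were 5.26 ± 0.97 at day 7 and 3.51 ± 0.38 at day 4, without overlap (exact permutation p = 0.0286, 0.147 adjusted over 36 lists). Skeletal muscle scores were 6.41 ± 2.82 and 4.43 ± 1.53 (exact permutation p = 0.286). By the same limit, the 8 largest falls were Krt24 (-5.42 ± 1.43), the hair keratin-associated genes Krtap5-4 (-5.27 ± 1.56) and Krtap12-1 (-4.98 ± 1.50), Krt2 (-5.03 ± 1.10), Lyg2 (-4.87 ± 1.41), Bhmt (-4.79 ± 1.16), Cyp2b23 (-4.45 ± 0.75) and Mt4 (-4.07 ± 0.75). Adjusted p over these 16 genes lay between 0.0052 and 0.046.

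Il17a, Il17f and Il22, the effector cytokines of the IL-23/IL-17 axis, rose with adjusted p of 0.045, 0.041 and 0.044, and 6 of the 23 list members rose and 1 fell. Their day 4 values were close to the detection limit: LPC libraries held 4 summed counts of Il17a at day 4 and 177 at day 7, a ratio of 46.6 after scaling to library size, with a 95% Clopper-Pearson interval of 17.9 to 173 that covers counting error only. For Il22, 3 and 160 counts gave 56.2 (18.9 to 275), and for Il17f 31 and 513 counts gave 17.4 (12.1 to 25.9). LPC day 7 mouse 1 held 120, 85 and 295 of these day 7 counts of Il17a, Il22 and Il17f, and without it the ratios were 19.3 (7.15 to 73.4), 33.9 (11.2 to 168) and 9.54 (6.53 to 14.4). Without that mouse the edgeR adjusted p was 0.096 for Il17a, 0.075 for Il22 and 0.080 for Il17f, so none of these calls held, and each of the 3 ended in 7 of the 8 fits without a single LPC mouse. Of 23 genes of interferon gamma response and antigen presentation 10 rose and 4 fell. The guanylate-binding protein genes Gbp2 (3.29 ± 0.48) and Gbp4 (2.40 ± 0.44) rose, whereas the class II antigen presentation gene H2-Aa fell by 1.07 ± 0.23. Among 17 inflammasome genes 5 rose, including Gsdmd, which encodes the pore-forming gasdermin D (1.52 ± 0.34), and Casp4 (2.15 ± 0.55). In the list of LPC receptors and metabolism 6 of 28 rose and 1 fell, with Pla2g7 at 2.00 ± 0.25, Gpr65 at 3.06 ± 0.58, the LPC acyltransferase gene Lpcat1 at 0.78 ± 0.16 and Gpr132 at 1.11 ± 0.29. Of 22 endothelial genes 7 rose, with the cadherin gene Cdh5 at 1.50 ± 0.39. Endothelial scores were 4.48, 5.72, 4.57 and 5.38 in LPC day 7 mice 1 to 4, against 4.04 to 4.70 in LPC day 4, and interferon gamma scores 5.56, 6.22, 5.31 and 7.23 against 4.22 to 5.60, with the higher values in mice 2 and 4.

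Terminal differentiation genes fell in 8 of 29 cases and rose in 1, and 10 of 23 sebaceous gland genes fell, such as Far2 (-2.02 ± 0.44) and Awat1 (-2.14 ± 0.51). Of 11 melanocyte genes, 5 fell and Ednrb rose, with Pmel, a melanosome protein gene, at -2.96 ± 0.65 and Mlana at -3.24 ± 0.87. Of 15 clock genes 6 fell, led by Hlf (-2.31 ± 0.35) and Ciart (-1.72 ± 0.38). Cd207, which encodes the Langerhans cell protein langerin, fell by 2.26 ± 0.37 (adjusted p = 0.0045). Adjusted over the list alone, 22 macrophage, 18 type I interferon, 10 endothelial and 9 inflammasome genes rose, the last list with 1 fall, and 16 sebaceous genes fell with 1 rise and 11 clock genes fell. The corresponding counts of rises and falls were 8 and 2 for IL-23/IL-17, 14 and 5 for interferon gamma, 6 and 5 for LPC metabolism, 4 and 13 for terminal differentiation, and 1 and 7 for melanocyte genes. Camera called the macrophage (adjusted p = 8e-11), type I interferon (7e-09), interferon gamma (0.00069), inflammasome (0.00026), endothelial (0.00011) and IL-23/IL-17 (0.035) lists upwards. Sebaceous (1.3e-08), clock (1.3e-07), melanocyte (0.0001) and terminal differentiation (0.0012) lists were called downwards, and the LPC metabolism list was not called (adjusted p = 0.15). With an estimated correlation, the lowest adjusted p of these lists was 0.48 and no list was called.

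The count of 1736 genes became 819, 518 and 526 without LPC day 4 mouse 1, 2 or 3, and 820 and 1136 without LPC day 7 mouse 2 or 4. It was 888 with the muscle score as a covariate, 1100 with the 8 LPC libraries alone, 799 by limma-voom and 3073 by DESeq2, and FPKM values turned the balance to 583 rises and 1035 falls with a pseudocount of 0.1, and 576 and 939 with 1, where the median log2 fold change of all genes was -0.12 and -0.08, against 0.03 for the counts.

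The test of whether the LPC effect differed between the days called no gene. Genes with the lowest adjusted p were Tbx3 (interaction 2.26 ± 0.32 on the log2 scale) at 0.058, and Btg2, an antiproliferative immediate early gene (1.48 ± 0.27), at 0.074. Krt10 had -2.93 ± 0.58 (adjusted p = 0.11), Pla2g7 1.68 ± 0.35 (adjusted p = 0.11) and Selp, the endothelial adhesion gene P-selectin, 3.11 ± 0.71 (adjusted p = 0.13). edgeR called 0 of 15782 genes and found 2674 at an unadjusted p under 0.05, against 585 called by DESeq2, 9 by limma-voom and 1 each with median-of-ratios size factors in edgeR or with log2(FPKM + 1).

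As lists, terminal differentiation genes had a lower LPC effect at day 7 than at day 4, by a median of -1.19, with none of 29 members past the threshold over all genes and 10 lower when adjusted over the list alone. Camera gave an adjusted p of 8.4e-11, fry 0.016, and adjusted p = 0.12 was found with an estimated correlation. Krt1 had -2.24 ± 0.60 (adjusted p = 0.16). For skeletal muscle genes, the LPC effect had a median of -4.02 at day 4 and 0.33 at day 7. The muscle score at day 7 was not higher with LPC (LPC minus vehicle -0.91, exact permutation p = 0.6). The median difference between days was 4.27, with 23 of 25 members higher when adjusted over the list alone, such as Des (desmin, 4.27 ± 1.25, adjusted p = 0.17). Camera gave an adjusted p of 8.6e-13, or adjusted p = 0.59 with an estimated correlation. Of the type I interferon genes 12 of 25 were higher when adjusted over the list alone (camera adjusted p = 1.9e-11, and adjusted p = 0.59 with an estimated correlation). Without vehicle day 4 mouse 3, edgeR called 214 genes in this comparison, without vehicle day 7 mouse 1 it called 3 and without vehicle day 7 mouse 4 it called 1.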

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

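The tests of other splits of the libraries, of muscle content and of epidermis content were chosen after the results were seen, while the test of the hour of killing was set before its result was seen.

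At day 4, 1 of the 35 splits of the 8 libraries into groups of 4, the real one, called as many as 22 genes. The highest other split called 1. This is the smallest share that 35 splits can give, so chance is less likely for this count but not excluded. The skeletal muscle score differed between these groups (8.74 ± 1.70 with vehicle, 4.43 ± 1.53 with LPC). With it as a covariate, the 15 genes that rose kept a median share of 0.9 of their log2 fold change (quartiles 0.84 and 0.99). Because that score and LPC change together, the share does not settle whether less muscle was a source of the rises of these 15 genes. Their median absolute log2 fold change went from 1.78 to 1.65 and the median standard error from 0.32 to 0.43, while genes with an unadjusted p below 0.05 went from 3025 to 1181 of all those tested; 0 of the 15 stayed called, all 15 kept an unadjusted p below 0.05, and which of these shifts ended the calls was not tested. For the 7 genes that fell the share left was 0.66 (quartiles 0.52 and 0.76), with the median absolute change going from 2.27 to 1.29, and muscle content and LPC cannot be told apart, because the muscle score itself differs between the groups. A direct effect of LPC on repair and stress genes remains a hypothesis, and whether LPC lowered muscle transcripts or less muscle was dissected stays open and untested.

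At day 7, 2 of the 35 splits called as many as 604 genes, so chance cannot be excluded for this count. The other split, which set vehicle mice 1 and 2 with LPC mice 1 and 3 against the remaining 4, called 1529 genes, which points to a structure of the samples, and it also parts them by skeletal muscle score (at most 7.46 against at least 7.69). With the muscle score as a covariate the 604 genes kept a median share of 1.01 of their log2 fold change (quartiles 0.97 and 1.06). Of these genes, 584 stayed called. The muscle score itself differed by -0.91 between the groups (LPC minus vehicle, exact permutation p = 0.6), with an SD of 2.82 within LPC day 7. At n = 4 and with that spread, the test cannot show that muscle content was equal. How much the covariate should have taken away is therefore unclear. The share therefore does not settle what muscle content adds to the changes of these genes. An even loss of epidermis in the LPC libraries would lower terminal differentiation and basal keratinocyte scores alike. Their difference per library was -1.78 ± 0.63 with LPC and -0.43 ± 0.37 with vehicle (mean ± SD, n = 4), a gap of -1.35 (exact permutation p = 0.0286). The terminal differentiation score alone already parted the groups, and the basal score differed by 0.15 (exact permutation p = 0.6). The gap therefore largely restates the fall that prompted the test. It goes against an even loss of all layers only. RNA of whole ear skin cannot tell fewer upper-layer cells from lower expression within them. Lower expression of differentiation genes within the epidermis remains a hypothesis, found and tested on the same libraries. What else differs with the structure of the samples stays open.

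The clock output genes Dbp, Hlf and Ciart were lower with LPC at day 7, and a different hour of killing between the groups would raise Arntl, Npas2 and Clock, which peak in antiphase. Their mean log2 fold change was 0.03 ± 0.11 (2 SE range -0.19 to 0.25), below the bound of 0.5 set in advance, which by that rule counts against the hour of killing. The SE combines the edgeR standard errors of the 3 genes as if independent, although they share libraries. Other clock genes were not flat: Cry1 had 0.81 ± 0.35 (edgeR unadjusted p = 0.037, adjusted p = 0.21), Per3 -1.21 ± 0.34 and Per2 -0.73 ± 0.32. The hour of killing is therefore not excluded. Whether tissue damage, inflammation or the structure of the day 7 libraries accompanies the lower output genes was not tested.

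For the remaining comparisons, 1 of 35 splits of the LPC libraries by day called as many as 1736 genes, with 3 in the highest other. Here too the share is the smallest that 35 splits can give, so chance is less likely but not excluded. All 35 splits of the vehicle libraries reached the real count of 0, with 198 in the highest other. Of 100 splits drawn for the difference of the LPC effect between days, all 100 reached the real count of 0 and the highest other called 1718. A count of 0 is reached by every split, so neither of the last tests bears on chance, and what sets apart the split with 1718 genes was not traced.

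Single libraries stood apart from the other 3 of their group in 29 of 408 groups of 4 values over 102 measures (7.1%, where chance gives about 5%). Vehicle day 4 mouse 3 had low scores of neutrophil (1.21, others 4.36 to 4.54), endothelial (4.25, others 4.66 to 4.74), adipocyte (4.39, others 5.83 to 6.08) and skeletal muscle genes (6.20, others 9.32 to 9.80). In the same library, log2 CPM was 1.49 for Il1b (others 6.27 to 7.22), 1.93 for Gpr132, 0.44 for Asb16, 2.66 for Gmpr and 0.44 for Actc1, each below its group. Vehicle day 7 mouse 4 had a low psoriatic keratinocyte score (5.03, others 7.44 to 7.81), 6.51 for S100a8 (others 10.35 to 10.94) and 6.40 for S100a9 (others 10.94 to 11.50), but high Mt4 (6.74, others 4.94 to 5.14) and a high Schwann cell score (5.04, others 3.89 to 4.03). Vehicle day 4 mouse 3 and vehicle day 7 mouse 4 had a Pearson correlation of log2 values of 0.9618. Correlations of vehicle day 4 mouse 3 with its own group were lower, at 0.8774 to 0.90.

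Above their groups on the log2 CPM scale were Adm in vehicle day 4 mouse 4 (3.99), Adh6a in LPC day 7 mouse 4 (3.93), Tmem8c in LPC day 4 mouse 4 (-0.83), Krtap12-1 in LPC day 7 mouse 3 (0.38), Gpr132 in LPC day 7 mouse 1 (4.23) and Il22 in LPC day 4 mouse 1 (-1.93) and LPC day 7 mouse 1 (2.38). Below their groups were Atf3 in LPC day 4 mouse 2 (5.88), Nos2 in LPC day 7 mouse 2 (3.84), Krtap5-4 (1.30) and Lyg2 (1.30) in vehicle day 4 mouse 4, Tnf in vehicle day 4 mouse 2 (2.97) and S100a9 in LPC day 4 mouse 3 (7.79, others 10.17 to 10.33). Scores also stood apart for oxidative stress genes in LPC day 4 mouse 3 (5.78, others 5.61 to 5.63) and for B and plasma cell genes in LPC day 4 mouse 1 (2.11, others 1.85 to 1.87).

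The LPC effect differed between day 7 and day 4 by camera for 19 of 36 lists, and for none with an estimated correlation (lowest adjusted p = 0.12). The median of the members' log2 difference, day 7 minus day 4, was 4.27 for skeletal muscle, 2.89 for adipocyte, 2.56 for type I interferon, 1.86 for neutrophil, 1.56 for interferon gamma, 1.40 for macrophage and 1.11 for chemokine genes. It was 0.95 for endothelial, 0.79 for NF-kB feedback, 0.76 for psoriatic keratinocyte and 0.74 for hair follicle genes. Negative medians were -1.21 for melanocyte, -1.19 for terminal differentiation, -0.97 for sebaceous gland, -0.72 for circadian clock, -0.46 for sterol synthesis, -0.42 for oxidative stress, -0.26 for cell cycle and -0.23 for ribosomal protein genes.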

How the results depend on the processing

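The fits with 3 tissue scores as covariates, those without vehicle day 4 mouse 3 and LPC day 7 mouse 1 together, and the alternatives of list scores and of the genes called at both LPC days were chosen after the results were seen. Counts stayed within 1.5 times of the reported ones with median-of-ratios size factors and with the stricter filter, except for the difference between days, where size factors gave 1 gene in place of 0. The 22 genes of day 4 became 8 without a filter, 1104 with DESeq2, 1683 with limma-voom, 38 and 40 with FPKM (pseudocounts 0.1 and 1), 1333 with the day 4 libraries alone, 0 with the muscle covariate, 0 with 3 covariates and 928 without the 2 libraries, and 0 to 683 without any single library. The 604 genes of day 7 became 1448 with DESeq2, 178 with limma-voom, 45 with the day 7 libraries alone, 1175 with the muscle covariate, 1577 with 3 covariates and 229 without the 2 libraries, and 111 to 697 without any single library. DESeq2 also called all 22 genes of day 4 and all 604 of day 7. The 0 genes of vehicle day 7 against day 4 became 223 with DESeq2, 2489 with limma-voom and 0 to 205 without a single library. For LPC day 7 against day 4, 1736 genes became 3073 with DESeq2, 799 with limma-voom, 1100 with the LPC libraries alone, 888 with the muscle covariate and 760 with 3 covariates, and 518 to 2207 without a single library. For the difference between days, 0 genes became 585 with DESeq2, 9 with limma-voom, 1 with log2(FPKM + 1) and 532 without the 2 libraries, and 0 to 214 without a single library. The 5 genes called at both LPC days became 2 without a filter, 111 with DESeq2, 15 with limma-voom, and 0 each with the muscle covariate, with 3 covariates and with each day fitted alone. Fits without some libraries or groups also estimate the spread from fewer libraries. Fitting only the groups compared raised the day 4 count but lowered that of day 7. The main fit shares dispersions over all 16 libraries, although the spread differs between groups. Sample weights of limma-voom, lower for more variable libraries, were 0.42 to 0.57 in LPC day 7 and 1.29 to 1.74 in LPC day 4. They were 0.56 to 1.12 in vehicle day 4 and 0.41 to 4.87 in vehicle day 7. How far shared dispersions set the counts was not tested, nor was the cause for the other alternatives.

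Camera called 15 lists at day 4, 19 at day 7, 18 for vehicle over time, 22 for LPC over time and 19 for the difference between days. With an estimated correlation it called 0 in each of the 5 comparisons, and fry called 0, 9, 0, 4 and 1. Scores of 5 lists (skeletal muscle, adipocyte, hair follicle, terminal differentiation and neutrophil) were recomputed under other scalings and filters, and kept their side of the threshold except at day 4, where the muscle difference of -4.31 became -4.29 with log2(FPKM + 0.1) and -3.94 with log2(FPKM + 1), and the adipocyte difference of -1.94 became -1.91 with log2(FPKM + 0.1), each now at an exact permutation p of 0.0286. The hair follicle difference at day 7, not called at 0.22, turned to -0.10 with log2(FPKM + 1) (exact permutation p = 0.943). The cause was not tested. Of 3604 values of named called genes under the alternatives, 2268 kept their side of the threshold, 1336 lost it and 0 reversed. Of 1009 values of named genes that were not called, 150 passed the threshold under an alternative.

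With the mouse number as a replicate block, edgeR called 2 genes at day 4, 351 at day 7, 0 for vehicle over time, 901 for LPC over time, 0 for the difference between days and 2 at both LPC days. Deviations from the group means of same-numbered mice correlated at 0.099 to 0.539 between vehicle day 4 and LPC day 4, where 3 of 4 mice correlated best with their own number, and at -0.596 to 0.148 between the day 7 groups, where 0 did. The numbers therefore do not pair the mice of the day 7 groups. Between the day 4 groups, a factor shared by same-numbered mice cannot be excluded. Each mouse gave a single library. The depth limited statements on Il17a and Il22, which had 4 and 3 summed counts in the LPC day 4 libraries.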

Other observations

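With LPC, single members of further gene lists rose, and none of the tests of this part was chosen after the results were seen. The lists share members, so not every call below is a further gene. Dusp1 is also in the immediate early list, and Mmp13 and Thbs1 are also in the repair list. Of 24 chemokine genes at day 7, Cxcl1 rose over all genes and 13 rose when adjusted over the list alone, with the monocyte attractant Ccl2 at 1.54 ± 0.42 (adjusted p = 0.053) and Ccl3 at 2.85 ± 0.94 (adjusted p = 0.10). Camera gave adjusted p = 1.6e-05, and adjusted p = 0.19 with an estimated correlation. Among 26 psoriatic keratinocyte genes the protease inhibitor gene Slpi rose at day 7 (1.95 ± 0.46, adjusted p = 0.033), 2 rose when adjusted over the list alone, and camera gave adjusted p = 5.8e-07, or adjusted p = 0.45 with an estimated correlation. Of 23 interferon gamma genes at day 7, Nos2 and Gbp2 (1.83 ± 0.45) rose and 6 did when adjusted over the list alone, with a camera adjusted p of 0.00046, and adjusted p = 0.55 with an estimated correlation. Of 20 unfolded protein response genes Trib3 rose at day 7 (1.31 ± 0.31), 9 rose when adjusted over the list alone, and camera gave adjusted p = 9.1e-07, or adjusted p = 0.30 with an estimated correlation. Among 14 glucocorticoid response genes Dusp1 rose at day 7 and 5 rose when adjusted over the list alone (camera adjusted p = 0.0046, and adjusted p = 0.28 with an estimated correlation). Of 30 fibroblast and matrix genes, Mmp13 and Thbs1 rose at day 7 and 3 did when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.60 with an estimated correlation). At day 4 none of the 30 passed and 4 rose when adjusted over the list alone, with the collagen gene Col6a3 at 1.15 ± 0.29 (adjusted p = 0.067). In the endothelial list, 2 of 22 members rose at day 7, Angpt2, a vessel-remodelling factor (1.56 ± 0.30), and Vegfa, the vascular growth factor (1.75 ± 0.39). Adjusted over the list alone, 3 rose (camera adjusted p = 0.0028, and adjusted p = 0.52 with an estimated correlation). The list score differed by 0.38 (exact permutation p = 0.314), so these 2 genes do not show a change of endothelial content.

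Between day 4 and day 7 of LPC injection, some cytotoxic lymphocyte, keratinocyte activation and matrix transcripts rose. Of 18 T and NK cell genes, Gzma (6.52 ± 1.78), Gzmb (3.56 ± 0.94) and 2 others rose, and Cd28 fell by 1.49 ± 0.39, with 6 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation). With vehicle over time, 16 of the 18 were higher and 2 lower, and 0 passed over all genes (camera adjusted p = 0.032, and adjusted p = 0.72 with an estimated correlation). Gzma was uneven, at 0.181 and 0.272 CPM in LPC day 7 mice 1 and 3 and 6.62 and 14.1 CPM in mice 2 and 4, which had the higher muscle scores. Of 26 psoriatic keratinocyte genes 5 rose, such as Saa3 (3.49 ± 0.74) and Krt6a (2.25 ± 0.61), and 17 did when adjusted over the list alone (camera adjusted p = 1.3e-08, and adjusted p = 0.48 with an estimated correlation). With vehicle over time, 21 of these 26 genes were higher and 5 lower, and 0 passed over all genes. Their median log2 fold change with vehicle was 1.13 (camera adjusted p = 2.3e-05, and adjusted p = 0.65 with an estimated correlation). Of 24 chemokine genes 4 rose and 1 fell, among them Cxcl9 (4.08 ± 1.08) and Ccl17 (-2.69 ± 0.69), and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.55 with an estimated correlation). Of 30 fibroblast genes 6 rose, including Col3a1 (2.37 ± 0.68), and 10 did when adjusted over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.56 with an estimated correlation). This list leaned upwards to a like degree without LPC. Its median log2 fold change over time was 0.81 with LPC and 0.83 with vehicle, with 26 members higher and 4 lower in each. In the dendritic cell list 2 of 19 rose and Cd207 fell, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.43). Of 11 mast cell genes Hdc rose (2.11 ± 0.61), also when adjusted over the list alone, but Hdc is in the neutrophil list as well. Of 22 fatty acid synthesis genes 3 rose and 2 fell, with the same counts when adjusted over the list alone, among them Scd2 (1.21 ± 0.26) and Elovl3 (-1.68 ± 0.42). Sox9, of 17 cartilage genes, fell by 1.38 ± 0.27, and of 15 Schwann cell genes Egr2 (-1.37 ± 0.41) and Ncmap (-1.60 ± 0.48) fell, with the same counts when adjusted over the list alone. Egr2 is in the immediate early list as well. None of 6 B and plasma cell, 8 erythrocyte, 22 sterol synthesis and 30 ribosomal protein genes passed over all genes in any of the 5 comparisons with edgeR; adjusted over the list alone, 2 B and plasma cell genes rose and 1 fell between the days of LPC, and 1 sterol gene was lower in the difference between days. Camera placed sterol synthesis (adjusted p = 0.00069, and adjusted p = 0.55 with an estimated correlation) and Schwann cell genes (adjusted p = 0.00068, and adjusted p = 0.45 with an estimated correlation) below other genes with LPC at day 7. At day 4 camera placed ribosomal protein genes above other genes with a median log2 fold change of 0.26 (adjusted p = 5.7e-05, and adjusted p = 0.80 with an estimated correlation).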
